A study of Rattus norvegicus with 42 samples.

How the data were processed

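The submitters deposited 1 table of read counts per gene and 1 table of FPKM values for 42 libraries of rat intestine. Their processing notes name the genome build Rnor_6.0, HTSeq and DESeq2, without versions or roles. The aligner is not given in the sources used here. The counts were whole numbers for 32545 annotated genes, of which 9819 had no count in any library. In every library all FPKM values lay within 1% of the count divided by gene length and by library total, times 1 constant that ranged from 0.881 to 1.176 between libraries. A table row is 1 gene identifier, and 4708 rows shared a symbol with another row. Coordinates are 1-based positions on Rnor_6.0 from the deposited annotation.

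Groups were read from the library titles, which give the region, an animal code with D for DSS or C for control, and M or F. The treatment tag contradicts the title in 18 libraries of 6 animals, so groups by the tag were fitted as alternatives. Title and tag agree in DSS males 1 to 4, DSS female 4 and control females 1 to 3, so the fit of these 5 DSS and 3 control animals holds no control male, and DSS goes with sex in it. The tissue tag says colon for every library, also where the title and the design text say distal ileum. Libraries with the same animal code were read as the 3 regions of 1 animal.

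Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the low-count filter filterByExpr and the quasi-likelihood F test. Each region was fitted alone with the means of 4 groups, DSS or control by M or F. The DSS effect was the mean of the difference over M and F. DSS effects of different regions were compared in a fit over all libraries, with 1 term per animal and terms for region, region by sex and region by DSS. Regions in controls were compared over the control libraries alone, with 1 term per animal and a term for region. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and unadjusted counts at p under 0.05 are given where few or no genes were called. Alternatives used limma 3.58.1 on log2 of FPKM plus 1, and DESeq2 1.42.0. SE is the standard error of a log2 fold change, computed from the fitted value and its F statistic. Values given as mean ± SD are CPM (counts scaled to a common library total) after TMM scaling within the region. Region markers, Y-linked counts and sums of acinar transcripts are CPM of the library total. A fold against a group with no count was computed against a floor of 3 counts over the group, which covers counting error only.

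Before the data were examined, 13 gene lists and 22 cell type lists were fixed, with 681 symbols, of which 647 were found in the table. The gene lists were type 1 immunity, type 2 immunity, type 3 and 17 immunity, acute inflammatory mediators, interferon response, extracellular matrix remodelling, tight junction and epithelial adhesion, fatty acid oxidation and ketogenesis, oxidative phosphorylation, xenobiotic and steroid metabolism, hypoxia and glycolysis, endoplasmic reticulum stress, and cell division. The cell type lists were neutrophil, monocyte and macrophage, mast cell, eosinophil, T cell, B cell, plasma cell, goblet cell, colonocyte, ileal enterocyte, Paneth cell, stem and crypt base, enteroendocrine cell, tuft cell, fibroblast, endothelial cell, smooth muscle, enteric neuron and glia, adipocyte, stratified squamous epithelium, pancreatic acinar cell, and erythrocyte. Lists with at least 5 measured members were tested with camera of limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A directional test with fry was an alternative. The median of a list is the median log2 fold change of its measured members.

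The genes named below also follow a rule fixed at that time. It takes, for each region, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM, the same sign in M and F and a symbol that is not a bare identifier. It adds up to 4 members with the smallest adjusted p of each called list, and 19 immune genes in every region whether called or not. For the other contrasts it takes up to 5 genes in each direction. Genes that 2 parts of the rule name count under both, and the text names a part of them.

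In a simulated check, 100 genes in each comparison were changed 2-fold and 100 others 4-fold in simulated counts. For DSS against control, a 2-fold change was called in 49% of such genes in the distal ileum, 62% in the right colon and 63% in the left colon. A 4-fold change was called in 78%, 80% and 78%. Of the unchanged genes, 5 of 15596, 7 of 15703 and 4 of 15680 were called. For the difference of the DSS effect between M and F, a 2-fold change was called in 1%, 12% and 0% of genes, and a 4-fold change in 52%, 59% and 49%. Both list tests called 2 of 2 changed lists and 0 others. The simulated genes varied independently of each other, so this check cannot show false list calls that come from correlated genes.

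Other sets of libraries were fitted after the data were seen. The first leaves out 9 libraries whose region markers went against the region in their title, and the second holds the 21 libraries of males only. Without the 9 libraries each region keeps 7 DSS and 4 control libraries, with 1 control female, and the lone sample is assumed to vary like the other groups.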

Results

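RNA was sequenced from 3 gut regions of 14 Sprague Dawley rats, the distal ileum, the right (proximal) colon and the left (distal) colon. By the titles, 8 animals had drunk dextran sulfate sodium (DSS), a chemical that injures the colon epithelium, at 5.5% w/v for 6 days, and 6 were controls. RNA with an integrity number of at least 6.8 was used. There were 4 males and 4 females with DSS, and 3 of each sex without, which gives 14 libraries per region and 42 in all. Total counts per library ranged from 14273370 to 22842236 with DSS and from 15036007 to 34025610 in controls. Mitochondrial transcripts took 4.04% to 14.3% of the counts. They took 5.93% to 9.62% of the right colon counts in the 8 DSS libraries and 10.01% to 12.16% in the 6 control libraries, so this quality measure goes with the arms there. It also went with the arms in the male left colon, at 4.42% to 7.8% with DSS and 8.5% to 10.76% in controls. In the libraries titled female left colon it went the other way, at 6.54% to 8.64% with DSS and 4.04% to 5.69% in controls.

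Genes known to mark gut segments were read in each library as a check of the labels. Fabp6, the ileal bile acid binding protein, lay between 1601 and 6522 CPM in the 7 male ileal libraries. Car1, a carbonic anhydrase of the proximal colon epithelium, lay between 3504 and 12310 CPM in the 7 male libraries of the right colon. Hoxb13, a homeobox gene of the hindgut, lay between 171 and 372 CPM in the 7 male libraries of the left colon. In 9 of the 21 female libraries these markers went against the region in the title, by bounds of 1000, 1000 and 100 CPM that were chosen after the values were seen. The ileal library of DSS female 3 had Fabp6 at 2.79 and Hoxb13 at 233 CPM, its right colon library Fabp6 at 1110 and Car1 at 18.6 CPM, and its left colon library Car1 at 2165 and Hoxb13 at 2.35 CPM. The left colon library of control female 1 had Fabp6 at 2028 CPM, and its right colon library Hoxb13 at 510 CPM. The ileal library of control female 2 had Car1 at 11930 CPM. Control female 3 had Fabp6 at 1973 and Car1 at 5350 CPM in the ileal library, Car1 at 9099 and Hoxb13 at 162 CPM in the right colon library, and Fabp6 at 2084 and Hoxb13 at 89.3 CPM in the left colon library. The titles were kept for all libraries, and each comparison was also made without these 9 libraries and in males alone. The sum of 4 Y-linked genes, Eif2s3y, Kdm5d, Ddx3y and Uty, was 122 to 188 CPM in the 21 libraries titled M and 0 to 15.9 CPM in the 21 titled F. The highest F values were 15.9 CPM in the ileal library of DSS female 1, or 9.98% of the male mean, and those of DSS female 4. Her right and left colon libraries held 8.36 and 9.57 CPM, or 5.24% and 6.0%. All other F libraries held at most 1.47 CPM. The source of these Y-linked counts was not tested.

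**Figure D1:**
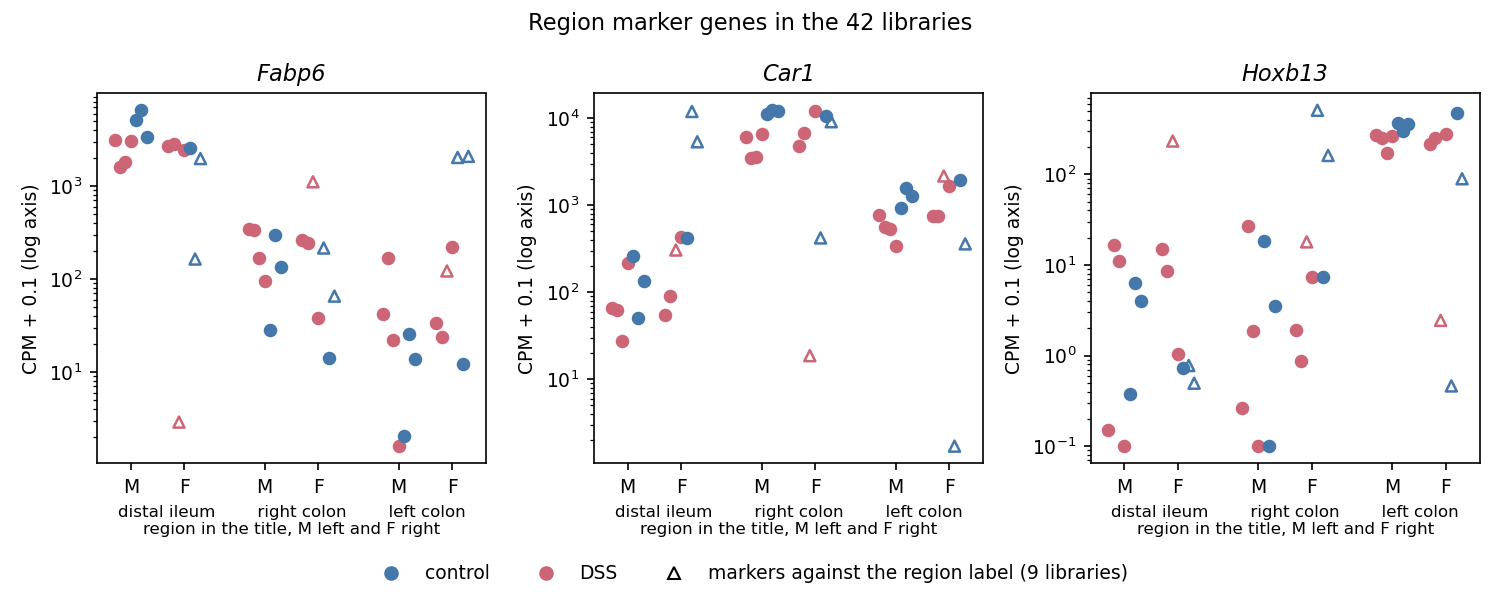
CPM plus 0.1 on a log axis of Fabp6, Car1 and Hoxb13 in each of the 42 libraries, by the region in the title and by M and F, with control in blue, DSS in red and open triangles for the 9 libraries whose markers went against their title. Male ileal libraries lie at 1601 to 6522 CPM of Fabp6, whereas the left colon libraries of control females 1 and 3 lie at 2028 and 2084 CPM.

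The first comparison asked how DSS changed each region, with type 2 immunity named in the title of the series. In the distal ileum, Ccl22, a chemokine that draws CCR4-bearing T cells, rose from 2.37 ± 0.958 CPM (SD, n = 6) in controls to 12.4 ± 3.18 CPM (SD, n = 8) with DSS, a log2 fold change of 2.44 with an SE of 0.20 (adjusted p = 1.67e-04). The gene ENSRNOG00000016535 lies at chromosome 19, 10674189 to 10681145. Il1rl1, the receptor of interleukin 33, rose from 5.20 ± 1.14 to 16.2 ± 7.94 CPM with the same n (log2 1.54, SE 0.26, adjusted p = 0.0176). Mmp10, a matrix metalloproteinase, rose from 25.8 ± 5.23 to 48.9 ± 11.8 CPM (log2 0.90, SE 0.13, adjusted p = 0.0117). Cyp4b1, a cytochrome P450, fell from 69.7 ± 14.1 to 16.1 ± 8.49 CPM (log2 −2.15, SE 0.30, adjusted p = 0.0117). Ccl22, Mmp10 and Cyp4b1 were called without the 9 libraries, in males alone, and without each of the 14 animals. Among animals whose title and tag agree Mmp10, Cyp4b1 and Il1rl1 were not called, and by the tag none of the 4 was. Il1rl1 was called in males (log2 2.24) and not without the 9 libraries (log2 1.52, adjusted p = 0.0800) or without control female 3.

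Other ileal calls rested on the libraries whose markers went against their title. The calcium-binding protein S100g fell from 588 ± 868 to 54.3 ± 29.0 CPM (log2 −2.53, SE 0.51), and its fold change was −0.85 without those libraries (adjusted p = 0.152). Cyp2c13 fell by log2 −3.05 (SE 0.59), against −1.26 without them, not called. Lct, which encodes lactase, differed by −2.57 (SE 0.71, adjusted p = 0.0660), and fell without the 9 libraries (log2 −2.75, adjusted p = 0.00313) and in males (log2 −4.03). The chemokine Cxcl6 rose by 4.86 (SE 0.85) and Il1b, an inflammatory cytokine, by 1.79 (SE 0.35) from 4.46 ± 1.97 to 15.1 ± 7.73 CPM. Without the 9 libraries they stood at 3.96 and 1.33 (adjusted p = 0.0523 and 0.117). The calls of S100g, Cyp2c13, Cxcl6 and Il1b were lost in 9, 9, 4 and 7 of the 14 fits without 1 animal, each of them also without control female 3.

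In all, 422 of 15796 tested genes were called in the distal ileum, 259 higher and 163 lower with DSS. Leaving out the 9 libraries gave 52 calls, 30 of them shared and in the same direction, and in males alone 1016. Leaving out control female 3 left 15 calls and leaving out DSS female 4 gave 1168, so single animals set the size of this count. DSS female 4 scored close to the control females over genes that changed with DSS in all regions of males, and was kept in every DSS mean. Of 14 called genes followed through the alternatives, 9 lost the call among the 8 animals whose title and treatment tag agree, and 14 when groups were read from the tag. The fit of those 8 animals holds 4 males, all DSS, and 1 DSS and 3 control females, so sex and the few animals bear on a call lost there.

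Of the lists fixed beforehand, 20 of 34 tested passed in the distal ileum, 14 upward. Acute inflammatory mediators had a median log2 fold change of 1.66, with 6 of 25 measured members risen and 19 when adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). Extracellular matrix remodelling had a median of 0.78, with 8 of 30 risen and 23 adjusted over the list alone (0.284 with an estimated correlation, as adjusted p). Type 2 immunity had a median of 0.47, with 5 of 21 risen, among them Ccl17 at 3.54 (SE 0.62), and 7 risen and 1 fallen adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). The Ccl17 call was lost without the 9 libraries (adjusted p = 0.0966), without DSS male 3 and without control female 3. That list was not called in males (adjusted p = 0.514). Type 3 and 17 immunity had a median of 0.49 with 3 of 16 risen and 7 adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). Cell division had a median of 0.66, with 2 of 23 risen, among them Mcm5 of the replication helicase at 0.89 (SE 0.20), and 19 adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). The Mcm5 call was lost in 10 of the 14 fits without 1 animal, without the 9 libraries (adjusted p = 0.175), with the FPKM values, with the smooth muscle covariate and where title and tag agree.

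Cell type lists with upward calls in the distal ileum were neutrophil (median 0.86, 3 of 14 risen, 6 over the list alone), monocyte and macrophage (0.65, 2 of 17, 10 over the list alone), mast cell (0.57, 3 of 13, 3 over the list alone), T cell (0.55, 2 of 18, 5 over the list alone), tuft cell (0.56, 3 of 16, 3 over the list alone), fibroblast (0.55, 3 of 15, 6 over the list alone), endothelial cell (0.57, 3 of 12, 7 over the list alone), stem and crypt base (0.38, 1 of 14, 1 over the list alone) and pancreatic acinar cell. Ptgs1, a cyclooxygenase of tuft cells and other cells, rose by 0.70 (SE 0.12) and Plvap, of the endothelium of small vessels, by 1.44 (SE 0.24). Both calls were lost without control female 3 and where title and tag agree, and that of Plvap without the 9 libraries (adjusted p = 0.0514). Downward calls were xenobiotic and steroid metabolism (median −0.48, 1 of 22 fallen, 4 over the list alone), ileal enterocyte (−0.36, 0 of 22, 0 over the list alone), B cell (−0.46, 0 of 14, 1 over the list alone), and adipocyte (−0.29, 0 of 12, 0 over the list alone). Fatty acid oxidation and ketogenesis (−0.29, 2 of 23) and colonocyte (−0.43, 0 of 21) were also called downward, with 2 and 1 members fallen over the list alone. With an estimated correlation 0 of the 20 lists passed by camera (adjusted p from 0.174 to 0.680), 4 had an unadjusted p under 0.05, and fry called 10. When the 9 libraries were left out the calls of fatty acid oxidation, colonocyte, stem and crypt base and adipocyte were lost, and in males those of type 2 immunity, fatty acid oxidation, mast cell, T cell, colonocyte and fibroblast.

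In the right colon Ccl22 rose from 2.15 ± 1.79 CPM (SD, n = 6) to 12 ± 4.73 CPM (SD, n = 8), a log2 fold change of 2.73 with an SE of 0.37 (adjusted p = 7.76e-04). Pla2g2a, a secreted antibacterial phospholipase, rose from 163 ± 63.4 to 1528 ± 783 CPM (log2 3.23, SE 0.41, adjusted p = 6.25e-04). Mmp3, which degrades extracellular matrix, rose from 0.173 ± 0.173 to 5.68 ± 2.05 CPM (log2 5.12, SE 0.52, adjusted p = 2.08e-04). Lcn2, an iron-sequestering protein of inflamed epithelium and neutrophils, rose from 1.05 ± 0.773 to 11.7 ± 4.65 CPM (log2 3.67, SE 0.50, and 6.77 without the 9 libraries, where 1 control female is left). Il22, a cytokine that acts on epithelium, had 1 count over the 6 control libraries and 336 over the 8 DSS libraries (adjusted p = 0.00160).

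The urea transporter Slc14a2 fell from 3.66 ± 1.68 to 0.244 ± 0.0914 CPM (log2 −3.85, SE 0.39, adjusted p = 2.08e-04) and the water channel Aqp8 from 57.2 ± 32.4 to 5.76 ± 8.04 CPM (log2 −3.75, SE 0.51). Slc26a3, the chloride and bicarbonate exchanger, fell from 1146 ± 162 to 615 ± 176 CPM (log2 −0.90, SE 0.19), and the butyrate transporter Slc16a1 by −0.87 (SE 0.18). Scgb1a1, a secretoglobin, fell from 221 ± 396 to 3.28 ± 3.48 CPM (log2 −4.65, SE 0.98), and was not called without the 9 libraries (log2 −2.70, adjusted p = 0.0827). In all, 2772 of 15903 genes were called, 1543 higher and 1229 lower. The fit without the 9 libraries called 2510, 1710 of them shared in direction, and in males 1634. The count ranged from 1840 without control male 3 to 3496 without DSS female 4, and among animals whose title and tag agree it was 1432. A smooth muscle score as covariate left 485 calls and ended those of Slc26a3 (adjusted p = 0.0947), Slc16a1, Ccl17, Scgb1a1, Spdef, Acadm, Cd79b, Synm and Cyp3a9, while animals whose title and tag agree ended those of Aqp8 (adjusted p = 0.0501), Acadm and Cd79b, and males those of Scgb1a1, Ccl17 and Synm.

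In the right colon 20 of 35 lists passed, 14 upward. Acute inflammatory mediators rose in 21 of 26 measured members (median 1.81, 22 over the list alone), among them Cxcl1, a neutrophil chemokine, at 6.53 (SE 0.80) and Il1b at 1.70 (SE 0.20), and this was the 1 list also called with an estimated correlation (adjusted p = 0.0221). The size of the Cxcl1 fold is uncertain, as the control females had no Cxcl1 count in the right colon. Cell division rose in 20 of 23 (median 0.94, 21 over the list alone), with the mitotic activator Cdc20 at 1.40 (SE 0.19, adjusted p = 0.190 with an estimated correlation for the list). Extracellular matrix remodelling rose in 19 of 30 (median 0.84, 23 over the list alone, adjusted p = 0.133 with an estimated correlation). Type 2 immunity rose in 7 of 23 (median 0.43, 8 over the list alone, adjusted p = 0.133 with an estimated correlation), with Il1rl1 from 4.05 ± 0.856 to 10.9 ± 2.91 CPM (log2 1.43, SE 0.23), Il4r, the receptor of interleukins 4 and 13, at 1.07 (SE 0.18), Ccr3, a receptor of eosinophils, at 3.30 (SE 0.65, and 5.99 without the 9 libraries) and Ccl17 at 3.01 (SE 0.73). Type 3 and 17 immunity rose in 7 of 16 (median 0.30, 7 over the list alone, adjusted p = 0.313 with an estimated correlation). Interferon response had 7 of 28 risen and 2 fallen (median 0.39, 10 and 2 over the list alone, adjusted p = 0.217 with an estimated correlation), with Gbp2 at 1.70 (SE 0.23), and was not called without the 9 libraries or in males.

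Goblet cell genes rose in 6 of 18 (median 0.44, 10 risen and 1 fallen over the list alone), with the secretory cell factors Atoh1 at 0.77 (SE 0.13) and Spdef at 0.66 (SE 0.16). Neutrophil genes had 7 of 15 risen (median 2.09, 8 over the list alone), with S100a9 at 4.38 (SE 0.63), monocyte and macrophage 8 of 17 (0.74, 13 over the list alone), mast cell 6 of 13 (0.94, 7 over the list alone), fibroblast 7 of 15 (0.45, 7 risen and 1 fallen over the list alone), endothelial cell 4 of 12 (0.48, 7 risen and 1 fallen over the list alone), T cell 2 of 18 (0.33, 0 over the list alone) and Paneth cell 2 of 8 (2.33, 4 over the list alone). Colonocyte genes fell in 8 of 22 and rose in 1 (median −0.51, 11 fallen and 1 risen over the list alone), B cell genes in 3 of 14 (−0.62, 3 over the list alone), with Cd79b of the B cell receptor at −1.02 (SE 0.24). Fatty acid oxidation fell in 6 of 23 (−0.30, 7 over the list alone), with Acadm at −0.70 (SE 0.15), oxidative phosphorylation in 6 of 23 (−0.22, 8 over the list alone), and smooth muscle in 4 of 16 (−0.15, 4 over the list alone), with the cytoskeletal Synm at −0.69 (SE 0.13). Xenobiotic and steroid metabolism had 4 of 22 fallen and 2 risen (−0.49, 6 and 2 over the list alone), with Cyp3a9 at −1.04 (SE 0.24). With an estimated correlation the adjusted p of the 19 lists other than acute inflammatory mediators lay between 0.133 and 0.49. The calls of T cell, interferon response and smooth muscle were lost without the 9 libraries, and those of fatty acid oxidation, xenobiotic metabolism, B cell and endothelial cell among animals whose title and tag agree.

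In the left colon the neutrophil chemokines Cxcl3 and Cxcl2 had no count in the 6 control libraries and were at least 559-fold and at least 666-fold higher with DSS. Cxcl3 reached 14 ± 7.66 CPM (SD, n = 8, adjusted p = 1.53e-04), and Cxcl1 rose from 0.405 ± 0.416 CPM (SD, n = 6) to 18.8 ± 13.7 CPM (log2 5.74, SE 0.53). Il1b rose from 4.92 ± 2.17 to 48.8 ± 54.5 CPM (log2 3.04, SE 0.55) and Il6 was at least 55.2-fold higher at 1.38 ± 1.22 CPM (adjusted p = 0.00449). Ccl22 rose from 1.42 ± 0.580 to 15.1 ± 5.45 CPM (log2 3.38, SE 0.32, adjusted p = 8.30e-05) and Ccl17, which binds the same receptor, from 0.443 ± 0.317 to 6.47 ± 2.66 CPM (log2 3.89, SE 0.44). Hk2, hexokinase 2 of glycolysis, rose from 149 ± 31.2 to 521 ± 176 CPM (log2 1.76, SE 0.16, adjusted p = 6.91e-05).

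Mrc1, the mannose receptor of macrophages, rose from 26.5 ± 10.51 to 78.6 ± 29.0 CPM (log2 1.61, SE 0.25), and Adipoq, the hormone adiponectin of fat cells, from 14 ± 11.4 to 42.2 ± 15.7 CPM (log2 2.12, SE 0.18). The homeobox gene Six4 fell from 2.63 ± 1.72 to 0.314 ± 0.215 CPM (log2 −3.07, SE 0.53), and Amn, of the vitamin B12 receptor, from 137 ± 128 to 11.8 ± 11.5 CPM (log2 −3.20, SE 0.56, and −2.36 without the 9 libraries). Cubn, the partner of Amn, fell from 45.4 ± 73.1 to 0.993 ± 1.1 CPM (log2 −3.19, SE 1.02), and stood at 3.68 without the 9 libraries, not called (adjusted p = 0.219). In all, 3741 of 15880 genes were called, 1924 higher and 1817 lower. With the 9 libraries left out 1959 were called, 1406 of them shared in direction, and in males 3117. Among animals whose title and tag agree 1971 were called, which did not include Il6, Six4, Mmp9, Mcm5 or Retnlb, and by the tag alone 8.

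For the left colon 17 of 35 lists passed, 14 upward. Acute inflammatory mediators rose in 24 of 28 measured members (median 3.10, 27 over the list alone) and extracellular matrix remodelling in 26 of 30 (1.36, 27 over the list alone), with Adamts4 at 3.10 (SE 0.36) and Plau at 2.18 (SE 0.26). Type 2 immunity had 12 of 25 risen and 1 fallen (median 1.61, 17 and 2 over the list alone), with Ccr3 at 3.41 (SE 0.65) and Il1rl1 at 1.13 (SE 0.25). Type 3 and 17 immunity had 8 of 17 risen and 1 fallen (median 1.45, 10 and 1 over the list alone), with Il22 at 6.93 (SE 0.91). These 4 lists each had an adjusted p of 0.192 with an estimated correlation. The size of the Il22 fold is uncertain, as the control females had no Il22 count in the left colon. Cell division rose in 10 of 23 (0.66, 15 over the list alone), with Mcm5 at 1.06 (SE 0.27), and hypoxia and glycolysis had 3 of 18 risen and 1 fallen (0.28, 3 and 1 over the list alone), with Pfkfb3, a regulator of glycolysis, at 1.21 (SE 0.15). With an estimated correlation these 2 lists had adjusted p = 0.628 and 0.411, and hypoxia and glycolysis was not called with the replicate block.

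Neutrophil genes rose in 11 of 15 (median 2.87, 12 over the list alone), with S100a9 at 5.51 (SE 0.92) and Mmp9 at 6.25 (SE 1.11), and monocyte and macrophage genes in 14 of 18 (0.95, 15 over the list alone), with the scavenger receptor Cd163 at 2.42 (SE 0.36) and the lectin Clec10a at 2.13 (SE 0.22). Fibroblast genes rose in 9 of 15 (1.15, 11 over the list alone), with Fap at 1.69 (SE 0.20), endothelial cell in 8 of 12 (0.77, 9 risen and 1 fallen over the list alone), with Vwf at 1.56 (SE 0.20), and mast cell in 3 of 14 (0.52, 5 over the list alone). Enteric neuron and glia rose in 7 of 18 (0.45, 7 over the list alone), with the glial filament Gfap at 1.60 (SE 0.30) and Tubb3 at 1.32 (SE 0.22), and adipocyte in 5 of 12 (1.03, 6 over the list alone), with Lpl at 1.49 (SE 0.18). Xenobiotic and steroid metabolism fell in 9 of 22 and rose in 1 (−0.62, 10 and 1 over the list alone), with the efflux pump Abcb1a at −1.55 (SE 0.28), against −0.92 without the 9 libraries and −0.53 in males, there not called (adjusted p = 0.139). Tight junction and epithelial adhesion fell in 8 of 24 (−0.34, 9 fallen and 1 risen over the list alone), with Epcam at −0.59 (SE 0.12) and Ocln at −0.64 (SE 0.15), and ileal enterocyte genes in 6 of 21 (−1.68, 8 over the list alone), with Fabp2 at −2.74 (SE 0.70). Without the 9 libraries Epcam, Ocln and Fabp2 stood at −0.39, −0.34 and 0.07 and in males at −0.21, −0.30 and −0.71, not called in either. Both of these lists lost the call without the 9 libraries, with medians of −0.11 and 1.15, and in males, with 0.14 and 0.68. With an estimated correlation 0 of the 17 lists passed by camera (adjusted p from 0.192 to 0.628), 5 had an unadjusted p under 0.05, and fry called 12 of the 17. The mast cell call was lost without each of 4 animals, and in males with that of adipocyte.

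**Figure D2:**
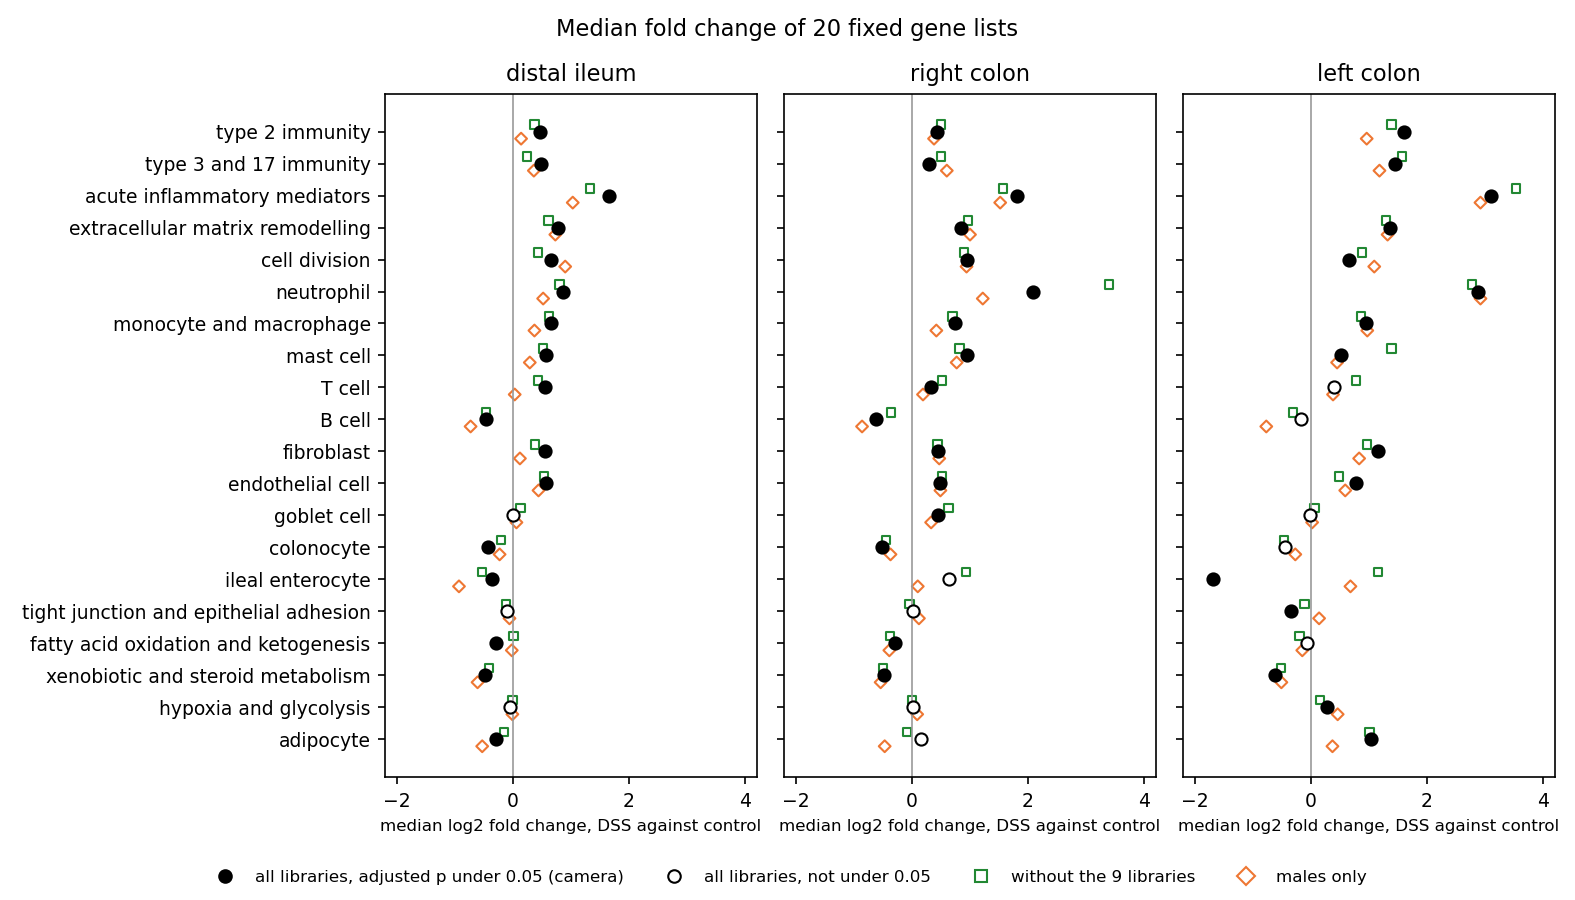
Median log2 fold change of DSS against control of the measured members of 20 of the lists in each region, as black circles that are filled where camera passed at an adjusted p under 0.05, with green squares for the fit without the 9 libraries and orange diamonds for males alone. Acute inflammatory mediators lie at 1.66, 1.81 and 3.10 in the distal ileum, right colon and left colon.

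The signature cytokines of type 2 immunity were hardly counted. Il4, Il5 and Il13 averaged at most 0.115 CPM in any group of a region, and neither they nor Il25 had enough counts for a test, so a difference was not detectable at this depth. Il33, the ligand of Il1rl1, was well counted and not called, at log2 0.12 (SE 0.18) in the distal ileum, −0.47 (SE 0.19, adjusted p = 0.109) in the right colon and 0.10 (SE 0.27) in the left colon. Its levels were 64.5 ± 5.64 CPM in control and 70.9 ± 28.1 CPM in DSS ileum, 96.8 ± 64.2 and 65.2 ± 10.9 CPM in the right colon, and 148 ± 64.0 and 154 ± 43.0 CPM in the left colon (SD, n = 6 and 8). Retnlb, a goblet cell protein induced by type 2 cytokines, rose in the left colon by log2 2.66 (SE 0.88, adjusted p = 0.0429), a call lost in 11 of the 14 fits without 1 animal, and differed by 3.45 (adjusted p = 0.0673) in the distal ileum and 0.10 in the right colon. Arg1, an enzyme of alternatively activated macrophages, differed by 1.83 in the left colon (SE 0.71, adjusted p = 0.0776). The values of Il33, Retnlb and Arg1 are of all libraries, with the 9 whose markers went against their title. Of the uncalled gene results followed through the alternatives, 2 changed sign without those 9 and 3 in males. Ifng and Il17a also had too few counts for a test.

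**Figure D3:**
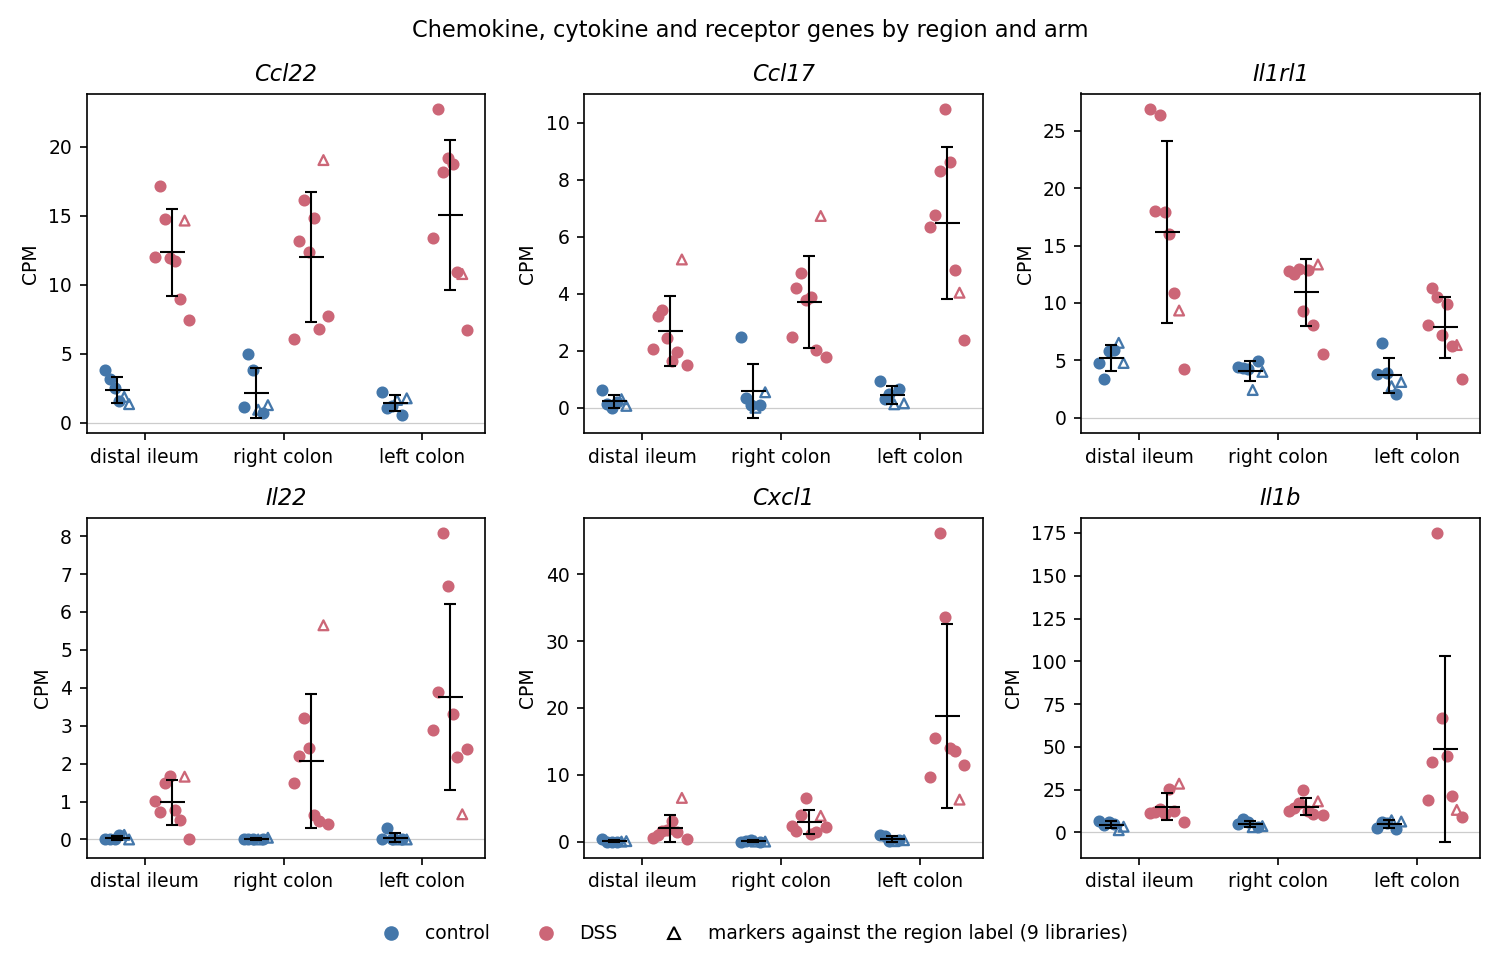
TMM-scaled CPM of Ccl22, Ccl17, Il1rl1, Il22, Cxcl1 and Il1b in each library, by region and arm, with the mean and SD in black. Ccl22 has means of 2.37, 2.15 and 1.42 CPM in the 6 control libraries of the distal ileum, right colon and left colon and of 12.4, 12 and 15.1 CPM in the 8 DSS libraries.

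Across genes, the DSS effects of the regions were compared with each other, with animals shared between regions and genes not independent replicates. Without the 9 libraries 12 of 14684 genes tested in all regions were higher with DSS in all 3 and 7 were lower. The 12 were Reg3g, an antibacterial lectin, Duox2 and Duoxa2 of the epithelial hydrogen peroxide system, Ccl22, Socs3, Mmp10, Igfbp4, Bfsp1, Cst7, Il18bp, Naip6 and Lgmn. The 7 were Rasgef1b, Gnai1, Stk17b, Pmp22, Samd8, Fam102a and Eepd1. These genes were listed after their values were seen. With all libraries 157 were higher and 59 lower in all 3 regions, of 15330 tested, and in males alone 210 were higher and 91 lower of 14587. Cst7, Il18bp and Fam102a were not among those of the males. The fold changes of distal ileum and right colon had a Pearson correlation of 0.56 over 15481 genes, those of distal ileum and left colon 0.61 over 15445, and those of right and left colon 0.62 over 15567. In 100 splits of the animals the median correlations were 0.06, 0.17 and 0.23 and the highest 0.55, 0.55 and 0.61. The covariances were 0.254, 0.327 and 0.378, against at most 0.196, 0.193 and 0.231 in other splits. Calls shared in direction numbered 266, 262 and 1474, against chance overlaps of 38.3, 50.1 and 327. The chance overlaps take the regions as independent, although the same animals gave all 3. Other splits shared at most 1, 0 and 0 calls. They mostly called few or no genes in a region, so these low numbers do not measure agreement between regions.

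The next question was whether the DSS effect differed between regions. Between left and right colon 4 of 16189 genes differed. Plat, tissue plasminogen activator, had a DSS effect higher in the left colon by log2 3.05 (SE 0.46, adjusted p = 0.00671) and Hmox1, heme oxygenase 1, by 1.48 (SE 0.24). Atoh1 and Hes6, both factors of secretory cell fate, had effects lower in the left colon by −0.83 (SE 0.13) and −1.03 (SE 0.17). Between left colon and distal ileum 107 genes differed, 54 with the higher effect in the left colon. Among them were Mgp, an inhibitor of calcification, at 2.51 (SE 0.40), Adipoq at 2.42 (SE 0.38), Scd1, a fatty acid desaturase, at 2.28 (SE 0.46) and A4galt at −1.54 (SE 0.28). Between right colon and distal ileum edgeR called 0 genes, with 1326 at an unadjusted p under 0.05 and 42 called by DESeq2. These 3 counts were 219, 990 and 301 without the 9 libraries, and in males 152, 1082 and 284. Angptl4, a lipoprotein lipase inhibitor, then stood at 5.17 (SE 0.67) for left colon minus distal ileum, against 2.79 with all libraries (adjusted p = 0.155), and Mmp9 at 7.22 (SE 1.26) against 2.55. Leaving out DSS female 3 alone gave 69, 834 and 13 calls.

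The DSS effect was also compared between the sexes. Pofut1 and Fam151a differed in the distal ileum, by log2 1.34 (SE 0.18) and −1.82 (SE 0.22) for M minus F, and neither was called without the 9 libraries. In the right colon 1 gene, annotated as Eif3h, differed by −7.24 (SE 0.75), and was not called without the 9 libraries (adjusted p = 0.0555). In the left colon edgeR called 0 genes, with 3179 at an unadjusted p under 0.05 and 1290 called by DESeq2. Without control female 2 edgeR called 3771, which cannot be read as a difference between the sexes. The left colon libraries of control females 1 and 3, which then stand for that group, had Fabp6 at 2028 and 2084 CPM. Between M and F themselves 22 genes differed in the distal ileum, 13 in the right colon and 290 in the left colon. The transcript XIST_intron, at X 74325012 to 74325079 beside the X inactivation gene, was lower in M in each region, by −9.09 (SE 0.57) in the ileum, and in the left colon it was not called without the 9 libraries (adjusted p = 0.251). The X-linked genes Eif2s3 and Kdm6a, known to escape inactivation, were lower in M by −0.74 (SE 0.08) and −0.92 (SE 0.11) in the right colon. The glycolytic regulator Pfkfb3 was higher in M by 1.26 (SE 0.14) in the ileum. Of the 200 genes lower in M in the left colon, the ileal hormone Fgf19 stood at −5.75 (SE 1.02), and 3 genes in all were called there without the 9 libraries.

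Regions were compared in the control animals. Between right colon and distal ileum 886 of 15424 genes differed, 383 higher and 503 lower in the colon. Muc1 and Muc4, membrane mucins, were higher in left colon than in distal ileum by log2 3.32 (SE 0.58) and 1.84 (SE 0.31), among 25 genes. Plin1 of lipid droplets and Vip, a peptide of enteric neurons, were lower in left than in right colon by −2.41 (SE 0.36) and −1.32 (SE 0.21), among 9 genes, all lower. That direction depended on the fit, as DESeq2 had 198 of 491 higher in the left colon, the fit without the 9 libraries 814 of 1822 and that of males 726 of 1704. Without the 9 libraries 3758, 4650 and 1822 genes differed, with 788, 25 and 9 of the first sets of calls shared in direction.

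Transcripts of pancreatic acinar cells, among them the lipase Pnlip and the protease Prss1, were counted in part of the libraries. The list was called upward in the distal ileum (median 7.67, 2 of 13 risen, 12 over the list alone, adjusted p = 0.403 with an estimated correlation) and in the left colon (10.13, 12 of 13 risen, 13 over the list alone, 0.628 with an estimated correlation, as adjusted p). Ctrb1 rose by 8.45 (SE 1.96) in the ileum and Prss1 by 12.60 (SE 3.25) in the left colon. The Ctrb1 call was lost in 11 of the 14 fits without 1 animal, without the 9 libraries (adjusted p = 0.184), with the FPKM values and with the smooth muscle covariate. Pnlip had no count in the 6 control left colon libraries and reached 85.4 ± 129 CPM (SD, n = 8) with DSS, at least 3405-fold higher (adjusted p = 0.0460). The Prss1 call was kept in males. It was lost without DSS female 2 (log2 7.41, adjusted p = 0.129), without control male 1 (adjusted p = 0.0581) and without the 9 libraries. That of Pnlip was lost in 7 of the 14 fits without 1 animal, with too few counts for a test in 3 others. Both were lost with the FPKM values and where title and tag agree, as was that of Ctrb1. The left colon call of the list was lost without the 9 libraries, without DSS male 1 and by fry, and the ileal call by fry. The sum of 13 acinar genes was at least 50 CPM in 15 libraries, 12 of them DSS, with a highest value of 12570 CPM in the right colon of DSS male 3 and a median of 24.8 CPM.

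**Figure D4:**
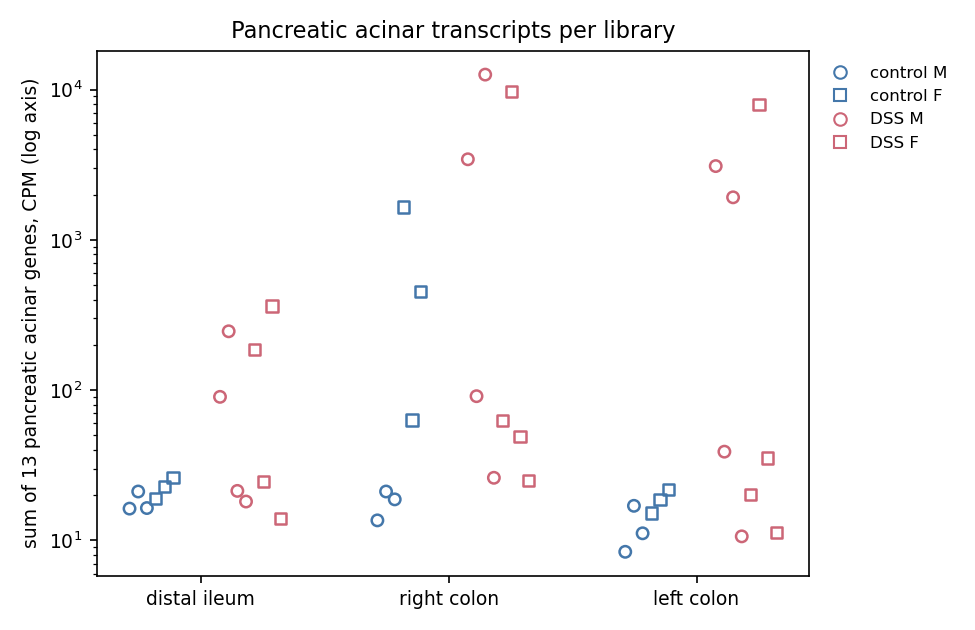
Sum of CPM of 13 pancreatic acinar genes in each library on a log axis, by region and arm, with 1 point per library. The highest point is the right colon library of DSS male 3 at 12570 CPM, and 15 libraries lie at 50 CPM or more.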

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

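The tests of region labels and treatment tags and the counts over other splits of the animals were written down after the results they measure had been seen.

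In 7 of 68 groups of 4 libraries, 1 library stood far from the other 3 for a gene whose mean is printed, where chance marks about 1 in 20 groups, or 3.4. In the distal ileum Cxcl6 was 47.1 CPM in DSS female 3 against 1.67 to 9.24 CPM in the other females, and S100g was 77.7 CPM in DSS female 3 against 32 to 38.3 CPM. S100g was also 117 CPM in DSS male 4 against 39.0 to 50.2 CPM in the other males. In the right colon Il22 was 5.65 CPM in DSS female 3 against 0.401 to 0.647 CPM, Il1rl1 was 9.33 CPM in DSS male 4 against 12.5 to 13 CPM, and Mmp3 was 8.49 CPM in DSS male 3 against 6.58 to 6.85 CPM. In the left colon Pnlip was 332 CPM in DSS female 2 against 0 to 0.133 CPM. Of these libraries, those of DSS female 3 in the ileum and right colon are among the 9 with markers of another region.

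Genes whose DSS effect differed between regions or sexes by the test of the difference were these. For left minus right colon, Plat stood at log2 3.05, Hmox1 at 1.48, Atoh1 at −0.83 and Hes6 at −1.03, and without the 9 libraries all 4 were called, at 3.25, 1.5, −0.89 and −1.0. For left colon minus distal ileum, Slc26a7 stood at 6.77, Mgp at 2.51, Plat at 2.43, Adipoq at 2.42, Scd1 at 2.28, Glp2r at −2.33, Gk5 at −2.30, Rhou at −1.55, A4galt at −1.54 and Acta1 at −1.45. Of these, Slc26a7 (4.72), Gk5 (−2.22) and Rhou (−1.45) were not called without the 9 libraries. For the DSS effect in M minus F, Pofut1 stood at 1.34 and Fam151a at −1.82 in the distal ileum and Eif3h at −7.24 in the right colon, and none of these 3 was called without the 9 libraries.

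Region markers went against the title in 9 female libraries and in 0 of 21 male libraries. Over 1167 genes, all 21 male libraries and 14 of 21 female libraries were closest to their own region. The reference regions were those of male libraries, so the male count is no separate check of the male titles. An exchange of titles may account for DSS female 3, whose 3 libraries were closest to 3 different regions, none its own, while the 3 libraries of control female 1 were closest to only 2 regions, which an exchange within that animal forbids. An exchange among the 6 libraries of control females 1 and 2 stays open, since each region then has 2 of the 6 libraries, and so does mixing of 2 regions in control female 3, whose lowest second share was 15.87% against at most 9.475% in male control libraries and 17.73% in male DSS libraries. No biological explanation was tested, and no library was moved to another region.

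The treatment tag says control for DSS females 1 to 3 and DSS for control males 1 to 3. If the titles of the control males were wrong, male D and C animals would not differ, but 3117 genes were called between them in the left colon, against at most 233 in the 34 other splits of the males. If the titles of DSS females 1 to 3 were wrong, their libraries would score like control females over the 210 genes higher and 91 lower with DSS in all 3 regions of males, but all 9 scored above every control female library, at −0.39 to 1.0 against −1.71 to −1.29, while DSS female 4, titled and tagged DSS, scored −1.47 to −1.03. Animals with the same tag thus differ by title in 2 of 2 sexes, so wrong tags with right titles are the explanation that may hold. Filling in the tags by position may be how they arose, because in the column order of the FPKM table the first 24 columns are tagged DSS and the other 18 control, which holds for 42 of 42 libraries.

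Counts of calls were compared with other splits of the animals. For DSS against control 1 of 100 splits gave as many calls in each region, the real one. It had 422, 2772 and 3741 calls against at most 34, 16 and 131 in other splits, so chance is unlikely. For the gene lists 8, 8 and 18 of 100 splits gave as many, with 20, 20 and 17 lists against at most 23, 22 and 22, so chance cannot be excluded for the number of lists in the distal ileum, right colon and left colon. For the DSS effect of left minus right colon and left colon minus distal ileum 1 of 32 splits gave as many each, the real one. It had 4 and 107 calls against at most 0 and 1. This is the smallest share that 32 splits can give, so chance is not excluded. As other splits called almost no genes, even the 4 calls rank first and carry little weight. For right colon minus distal ileum all 32 gave as many as the real 0. For the DSS effect in M minus F 9, 12 and 100 of 100 splits gave as many in distal ileum, right colon and left colon, with 2, 1 and 0 calls against at most 300, 19 and 516, so chance cannot be excluded. For M against F 1, 3 and 3 of 100 gave as many, with 22, 13 and 290 calls against at most 5, 70 and 1246. These shares are small, but sex-linked genes such as XIST_intron differ between the sexes whatever else does. The counts therefore do not test a wider sex difference, and in the right and left colon some other splits exceeded them. Splits by sex that called several times the real number point to a structure of the samples.

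For regions in controls 1 of 32 splits gave as many calls for right colon against distal ileum, the real one, with 886 against at most 1. This is the smallest share that 32 splits can give, so chance is unlikely but not excluded. For left against right colon 3 of 32 gave as many as the real 9, the highest being 1322 when the 2 colon titles of control females 1 and 3 are exchanged, and 312 when those of control female 1 alone are. For left colon against distal ileum 3 of 32 gave as many as the real 25, the highest being 1047 when the titles of control females 1 and 3 are exchanged. These splits cannot decide about chance, because each one that exceeded the real count exchanged titles of control female 1. Her right colon library was closest to the left colon of males (correlation 0.54). The left colon libraries of control females 1 and 3 were closest to the distal ileum (0.91 and 0.83). In males alone 1704 and 4870 genes were called for these 2 contrasts. How those female libraries came by their titles stays open. The counts of regions in controls were 886, 9 and 25 with all libraries and 3758, 1822 and 4650 without the 9.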

How the results depend on the processing

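The fits without the 9 libraries and in males were tests chosen after the data had been seen, while the other alternatives were planned, and for every changed result below the cause was not tested.

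For DSS against control 422, 2772 and 3741 genes were called in the distal ileum, right colon and left colon. An absolute log2 fold change of at least 1 left 166, 612 and 1228 of them. DESeq2 called 1376 in the distal ileum, no sex term 243 and the FPKM values 281 there. With the smooth muscle list as a covariate 145 were called in the distal ileum and 485 in the right colon. Libraries whose title and tag agree gave 146, 1432 and 1971, and groups from the tag 0, 7 and 8 by edgeR, the 0 with 1944 genes at unadjusted p under 0.05 (DESeq2 was not run by tag). Without the 9 libraries 52 were called in the distal ileum and 1959 in the left colon, and in males 1016 in the distal ileum and 1634 in the right colon. The animal number as a replicate block gave 1219, 2756 and 3771. Whether the numbers pair animals within a region was not settled. Residuals of libraries with the same number in other groups had median correlations of 0.0228, 4.89e-04 and −0.0110. In the distal ileum these ranged from −0.298 to 0.283, and 7 of 14 libraries were closest in residuals to one with their own number. In the right and left colon 3 and 2 of 14 were.

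For the DSS effect of left minus right colon DESeq2 called 90 genes, 219 were called without the 9 libraries and 152 in males, against 4. For right colon minus distal ileum these were 42, 301 and 284, against 0. For left colon minus distal ileum they were 455, 990 and 1082, against 107, with 57 at an absolute log2 difference of at least 1 and 15 with no animal block. Libraries of the same animal in other regions had a median residual correlation of 0.111 over 42 pairs.

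For the DSS effect in M minus F in the distal ileum 4 genes were called with no low-count filter and 226 by DESeq2, against 2. There 0 were called by edgeR with the replicate block (1994 at unadjusted p under 0.05) and 0 without the 9 libraries (1737), where DESeq2 was not run. In the right colon these 4 settings gave 2, 381, 3 and 15, against 1, and in the left colon DESeq2 called 1290, against 0. For M against F DESeq2 called 355, 230 and 1794 genes in the distal ileum, right colon and left colon, against 22, 13 and 290, and without the 9 libraries 14, 33 and 3 were called. The replicate block gave 12 in the distal ileum and 12 in the left colon, where an absolute log2 difference of at least 1 left 154. DESeq2 gave 25.9% of the calls in the distal ileum higher in M, against 54.5%.

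For left against right colon in controls 9 genes were called, 5 at an absolute log2 difference of at least 1, 491 by DESeq2, 1822 without the 9 libraries and 1704 in males. With no animal block 0 were called by edgeR, with 1922 at unadjusted p under 0.05. For right colon against distal ileum 886 were called, and those settings gave 457, 2773, 3758 and 3795, with 282 with no animal block. For left colon against distal ileum 25 were called, and they gave 14, 1187, 4650 and 4870, with 10 with no animal block. DESeq2 size factors kept every count within 1.5 times.

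Of the gene lists camera with an estimated correlation called 0, 1 and 0 in the distal ileum, right colon and left colon, with 4 and 5 at unadjusted p under 0.05 where 0 passed. In the distal ileum fry called 10 and groups from the tag 5, against 20.

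Leaving out 1 animal at a time gave 15 to 1168, 1840 to 3496 and 2624 to 5555 genes for DSS in the distal ileum, right colon and left colon, and 17 to 22, 19 to 23 and 16 to 25 lists. The DSS effect gave 2 to 69 genes for left minus right colon, 0 to 13 for right colon minus distal ileum and 13 to 834 for left colon minus distal ileum. The DSS effect in M minus F gave 0 to 38, 1 to 14 and 0 to 3771 genes, and M against F 9 to 225, 11 to 20 and 6 to 3858. Controls gave 0 to 200 for left against right colon, 0 to 1057 for right colon against distal ileum and 0 to 812 for left colon against distal ileum.

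By the treatment tag the direction turned for 18 of 57 called lists. In the distal ileum these had medians of −0.50 for acute inflammatory mediators, −0.27 for extracellular matrix remodelling, 0.03 for xenobiotic and steroid metabolism, −0.13 for cell division, −0.27 for neutrophil, −0.17 for monocyte and macrophage, 0.78 for ileal enterocyte, −0.28 for stem and crypt base, −0.30 for fibroblast, −0.01 for endothelial cell, 0.32 for adipocyte and −0.95 for acinar cell. In the right colon they were 0.14 for fatty acid oxidation and ketogenesis, −0.29 for cell division, 0.25 for B cell and −0.02 for endothelial cell, and in the left colon −0.54 for cell division and −0.99 for acinar cell. Ileal enterocyte genes in the distal ileum turned to 0.28 where title and tag agree. In the left colon they turned to 1.15 without the 9 libraries and to 0.68 in males, where tight junction and epithelial adhesion turned to 0.14.

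Of 79 called genes followed through the alternatives 15 turned by the tag. These were Cxcl6 (−2.19), Il1b (−0.50), Plvap (−0.01) and Ctrb1 (−0.72) in the distal ileum, and Il4r (−0.04), Lcn2 (−0.25), S100a9 (−0.12), Pla2g2a (−0.57), Acadm (0.15), Cd79b (0.07) and Cdc20 (−0.35) in the right colon. In the left colon they were Six4 (0.72), Prss1 (−0.68), Pnlip (−0.34) and Mcm5 (−0.32). Fabp2 (0.07) and Cubn (3.68) turned in the left colon without the 9 libraries. The calls of 64 others were weaker by the tag, and 0 of the 79 changed with DESeq2, DESeq2 size factors or no low-count filter.

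Too few counts left no value for Pnlip in the left colon in males, without the 9 libraries and without DSS female 2, DSS male 1 or DSS male 3, and for the acinar cell list of the distal ileum in males.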

Other observations

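The test of acinar transcripts, the score over genes of the males and the fits without the 9 libraries and in males alone were chosen after the data had been seen.

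Some gene groups moved further in the fits without the 9 libraries or in males, where each region held 7 DSS and 4 control or 4 and 3 libraries. Interferon response genes in the left colon had a median log2 fold change of 0.20 with all libraries, with 4 of 28 risen and 1 fallen (adjusted p = 0.0642). They rose in 13 of 28 without the 9 libraries with a median of 0.81, and in males in 16 of 28 with 0.89 (adjusted p = 0.253 without the 9 libraries and unadjusted p = 0.0509 in males with an estimated correlation). Type 1 immunity stood at medians of 0.05, 0.22 and 0.36 in the distal ileum, right colon and left colon, with 0, 2 and 1 members risen of 18 each, and was not called. It rose in the left colon without the 9 libraries (median 0.74, 3 of 18 risen, 4 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation). Smooth muscle genes in the left colon fell in males, in 11 of 16 members with a median of −0.68, against −0.12 with all libraries (unadjusted p = 0.0625 in males with an estimated correlation). Ileal enterocyte genes in the distal ileum fell in 11 of 22 members in males, with a median of −0.93, against −0.36 with all libraries and 0 members fallen (unadjusted p = 0.0537 in males with an estimated correlation).

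Other cell types were not called in any region with all libraries. Eosinophil genes had medians of 0.79, 0.34 and 0.86 in the distal ileum, right colon and left colon, with 1 of 7, 2 of 7 and 4 of 8 risen and 1 fallen in the left colon. Plasma cell genes had medians of 0.33, 0.08 and 0.21, enteroendocrine cell genes −0.26, 0.36 and 0.35, and erythrocyte genes 0.03, −0.06 and 0.26. Stratified squamous epithelium had 5 measured members in the colon, with medians of −0.21 in the right and 0.61 in the left colon, and was not tested in the distal ileum. Endoplasmic reticulum stress genes had medians of −0.05, 0.06 and 0.04, with 0, 6 and 5 of 21 risen and 2, 1 and 2 fallen.

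Over the 210 genes higher and 91 lower with DSS in all 3 regions of males, the libraries of DSS female 4 scored −1.47, −1.03 and −1.20 in distal ileum, right colon and left colon, against −0.39 or more in the other DSS females and at most −1.29 in control females. Its libraries thus lie close to those of control females although title and tag both say DSS, it is part of every DSS mean, and leaving it out moved the ileal count from 422 to 1168.

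Acinar transcripts were at 50 CPM or more in 15 libraries, with at least 9 of the 13 genes at 1 CPM or more in each. Pancreatic cells or their RNA in the sampled pieces are a candidate source, since the acinar genes stood in like proportions between these libraries (median correlation 0.8159 over the 13 genes). Reads carried over from the library with 12570 CPM are excluded as the whole source, as 6 other libraries lay above 10.01% of its sum, the largest share seen for Y-linked counts in female libraries. A difference between DSS and control animals cannot be told apart from chance, with a log2 difference of 2.24 and p = 0.08653 in an exact two-sided permutation test over 1225 arrangements of 8 and 6 animals. A biological difference with DSS stays open.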
